A study of Mus musculus with 64 samples.

How the data were processed

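RNA was measured in striatal punches of 16 adult C57BL/6J mice, 8 controls and 8 heterozygous knockouts of Hnrnph1, with 4 males and 4 females per genotype. Per the labels' protocols, punches of 3 mm from both hemispheres were pooled per mouse at about 50 to 80 days of age and kept in RNAlater for 24 hours. Stranded, polyA-selected libraries were read as 100 bp pairs on a HiSeq2500. Each mouse was sequenced in 4 runs over 3 flow cells, which gives 64 samples. The labels also give each mouse's cage (7 cages, 5 of them with both genotypes) and RNA integrity number, which was 10 for 14 mice, 9.8 for control mouse 1 and 8.3 for control mouse 11.

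The values deposited by the authors are whole-number counts of reads per gene and per exon bin, 1 file of each kind per run. Per the submitters' processing notes, HTSeq 0.6.1p1, FastQC 0.10.1, edgeR 3.8.6 and limma 3.22.7 were used, and the mm9 and mm10 builds are named without saying which file used which. The aligner, the annotation release and the strand setting of the counting are not given in the sources used here. The gene counts list 23420 symbols. The exon counts list 368092 bins of 36889 gene identifiers, of which 908 combine several genes, in the format of DEXSeq's counting script. Bin coordinates depend on the annotation the authors used, so bins are named here by number only. Gene coordinates are those of GENCODE M21 on GRCm38, 1-based, and were looked up by symbol. Because the strand setting is not stated, values of genes that overlap on opposite strands, such as Xist and Tsix, are uncertain.

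The 4 runs of a mouse were compared by a chi-square over genes for each of 96 pairs of runs. The chi-square per degree of freedom was 1.17 to 1.74 between runs of 1 mouse. Between mice of 1 genotype within 1 run it was 3.22 to 132 for controls and 2.70 to 14.3 for heterozygotes. Runs of a mouse were therefore summed and the mouse is the replicate throughout. The summed gene counts held 57676884 to 77543874 assigned reads per mouse and 10374155 to 24857695 per run. The exon counts held 92978437 to 124907218 per mouse. Reads outside any gene made up 48.1% to 53.0% of the lines of the gene counts, reads with several alignments 14.8% to 17.6% and reads ambiguous between genes 0.195% to 0.301%. These lines stayed out of library sizes and tests. The precision of each difference is given by its standard error between mice.

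Genes were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 on counts as deposited and summed, with TMM scaling, the default low-count filter of edgeR, sex as covariate and Benjamini-Hochberg adjustment at 0.05. The filter kept 16487 genes. Genotype within each sex and the interaction of genotype with sex came from 1 fit with a mean for each of the 4 groups. Levels of genes are CPM from the cpm function of edgeR on TMM-scaled library sizes, computed here. Levels of exon bins are CPM of a mouse's total bin counts, without TMM scaling. Standard errors are the log2 difference divided by the square root of the F statistic. Exon usage was tested with diffSpliceDGE of edgeR, which compares a bin's change with that of its gene. Of 223873 bins kept by the filter, 220898 in 14799 genes were tested, with Simes adjustment within genes. Gene lists were tested with camera of limma 3.58.1 on voom values, with its preset correlation of 0.01, again with an estimated correlation, and with fry. A list's score in a mouse is the mean over its genes of log2 CPM with a prior count of 2, centred on the mean of all mice. List medians are of edgeR's log2 differences unless voom values are named, as in all comparisons that leave out mice or add covariates. Score differences were tested by exact two-sided permutation of the mice. An index of transcript coverage was computed over 9030 protein-coding genes with at least 6 bins and 50 counts in each part. It is the log2 ratio of counts in the 3' and the 5' part of a gene's bins, centred on the median mouse and summarised as the median over genes.

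The groups, tests, 27 gene lists, rule for named genes and most other settings were chosen before the data were examined. The lists cover striatal neuron types, other brain cell types, neighbouring tissues, signalling, RNA-binding proteins, stress, sex and the 14 tested neighbours of Hnrnph1 on chromosome 11. Of the listed symbols, 6 were absent from the gene counts. The haemoglobin list kept 1 gene and was not tested as a list. The rule names Hnrnph1 first, then genes that pass, up to 10 per direction with a mean of at least 1 CPM, and, where fewer than 20 pass, those with the smallest p up to 20. It also names 2 to 4 members of each list with the smallest p, up to 5 genes per direction for the sex contrasts and the interaction, and up to 10 genes with changed exon usage. The number of 3 members per list was set after the data were seen, and the values of some members are not reported here. The coverage index, the tests of single list scores, the shares and levels of Hnrnph1 bins, the level of Hnrnph1 within cages, the relations of scores within a genotype and the genes named only for mouse 4, mouse 6 or mouse 9 were also chosen after the data were seen.

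The tests were tested on simulated data. For genes in 8 against 8 mice, 14 of 67 genes changed by 1.2-fold were called (20.9%), as were 55 of 67 at 1.5-fold (82.1%) and 64 of 66 at 2-fold (97%), with 8 unchanged genes called among 16422 tested. A shift of 0.1 on the log2 scale in the medium spiny neuron list was called, with 0 other lists called. Genes were simulated independently of each other there. The real list genes had estimated correlations such as 0.156 for medium spiny neurons and 0.941 for oxidative phosphorylation. The simulation therefore does not show how often camera calls lists of correlated genes by chance. For exon bins, 0 of 67 were called at 1.2-fold, 11 of 67 at 1.5-fold and 55 of 66 at 2-fold. There, 22 unchanged bins were called among 37670, and 20 unchanged genes among 1997, which is more than the nominal share of calls. The exon test therefore makes false calls beyond its nominal rate, and the cause was not tested.

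Other settings tried were other scalings, DESeq2 1.42.0, limma voom, other low-count filters (none, or at least 1 CPM in 8 mice), no covariate, cage as a block or random effect, consecutive mouse numbers as a block, single runs, all 64 runs with the mouse as a random effect, 2 surrogate variables from sva 3.50.0, gene counts summed over bins, a filter of 20 counts in 8 mice for bins, limma's diffSplice, the gene-level F test for exon usage, and leaving out each mouse. Sample quality weights, robust dispersions, leaving out several mice and covariates for list tests were added after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.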

Results

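Striatal RNA was compared between 8 control mice and 8 mice heterozygous for a knockout of Hnrnph1, which encodes an RNA-binding protein of the hnRNP family with a role in splicing. Each genotype held 4 males and 4 females, named here by the mouse numbers of the labels. Summed over 4 runs, the controls had 60409564 to 77204106 and the heterozygotes 57676884 to 77543874 reads assigned to genes per mouse (n = 8 each). Levels of genes are TMM-scaled CPM, and those of exon bins are CPM of a mouse's total bin counts, without TMM scaling. Differences are heterozygote minus control on the log2 scale unless stated otherwise.

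The knockout's target was measured first, in every mouse. Hnrnph1 (ENSMUSG00000007850, chromosome 11, 50376990 to 50386528, GRCm38) had 303 ± 53.3 CPM in controls and 272 ± 46.7 CPM in heterozygotes (SD, n = 8 each). Its log2 difference was -0.15 (SE 0.10), which did not pass edgeR's quasi-likelihood test (adjusted p = 0.75). In control mice 1, 3, 5, 7, 9, 11, 13 and 15 it had 317, 273, 298, 269, 428, 287, 264 and 287 CPM. In heterozygous mice 2, 4, 6, 8, 10, 12, 14 and 16 it had 250, 266, 383, 246, 231, 272, 260 and 271.5 CPM. The genotypes overlapped in this total. Without control mouse 9 the log2 difference was -0.07, and without heterozygous mouse 6 it was -0.23. Mice 6 and 9, with the highest level of each genotype, shared a cage. In each of the 5 cages with both genotypes, every heterozygote lay below every control, with log2 differences of -0.079, -0.075, -0.16, -0.049 and -0.126 (mean -0.098 ± 0.045, SD of 5 cages, 13 mice). The difference of -0.16 compared mouse 6 with mouse 9, whose transcript coverage was shifted to the 3' end. In mouse 9, exon bin 44 of Hnrnph1 was at 83.87 CPM, against 31.6 to 41.73 CPM in the other controls. Nearer the 5' end, its bins 14 and 15 were low, at 3.78 and 10.25 CPM, against 7.93 to 10.05 and 18.14 to 24.79 CPM. Its bin 18 was at 19.8 CPM, within their range (18.02 to 22.3 CPM). Whether that shift raised its total was not tested. An exact two-sided permutation of the genotypes within the 5 cages, this one included, gave p = 0.0093. It was chosen after the values were seen, and its 108 arrangements can give no smaller p. With cage as a block, edgeR gave Hnrnph1 -0.09 (adjusted p = 0.61). Of the 48 exon bins of Hnrnph1, 44 were tested and none passed the exon usage test of edgeR, with 4053 of all bins at an unadjusted p under 0.05. As shares of the gene's bin counts, 4 bins had an exact permutation p under 0.05, and none passed after Benjamini-Hochberg adjustment over 44 bins (n = 8 each). Bin 26 took 0.0131% ± 0.0065 in controls and 0.0257% ± 0.0071 in heterozygotes (exact permutation p = 0.0045, adjusted 0.16), and bin 23 took 3.30% ± 0.14 and 3.45% ± 0.053 (exact permutation p = 0.0075, adjusted 0.16). Bin 24 took 2.03% ± 0.077 and 2.12% ± 0.074 (exact permutation p = 0.031, adjusted 0.39). Bin 8 was lower in heterozygotes, with 2.17% ± 0.35 and 1.86% ± 0.12 (exact permutation p = 0.035, adjusted 0.39). Its usage by edgeR was -0.12 (SE 0.12) on the log2 scale with all mice and -0.20 (SE 0.065, p = 0.0020, adjusted p = 1) without control mouse 9.

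The level of bin 8 of Hnrnph1 itself was lower in heterozygotes, with 9.89 ± 0.76 CPM in controls and 7.72 ± 0.73 CPM in heterozygotes (SD, n = 8 each). This difference passed an exact two-sided permutation test (p = 0.00047, 0.021 after Benjamini-Hochberg adjustment over the 44 bins), a test chosen after the values were seen. The heterozygotes lay at 6.81 to 9.16 CPM and 7 of 8 controls at 9.75 to 10.93 CPM, while control mouse 9 was at 8.24 CPM. No bin separated all 16 mice. Without mouse 9, bin 8 was the 1 of 44 bins that separated the genotypes. For a single bin, chance gives this in 0.0311% of splits. Mouse 9 was left out and bin 8 was picked after their values were seen. The splits repeat neither choice, so this share leaves chance open. Without mouse 9 a lower level was not particular to bin 8. Bins 19 and 20 were also lower in heterozygotes then (exact permutation p = 0.00093 and 0.0016, adjusted 0.021 and 0.023). With all mice these bins did not pass that test (adjusted p = 0.45 and 0.16).

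**Figure D1:**
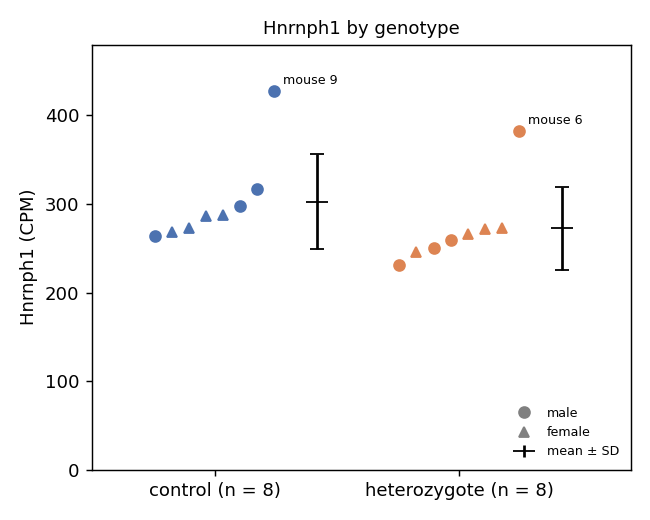
Hnrnph1 level per mouse in CPM (y axis) by genotype (x axis), with circles for males, triangles for females and bars for the mean ± SD of 8 mice. The genotypes overlap, and the highest values are 428 CPM in control mouse 9 and 383 CPM in heterozygous mouse 6.

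Across the striatal transcriptome, the genes with the smallest p between genotypes were mostly higher in heterozygotes, and no gene passed. Rasgef1b, an exchange factor for Ras-family GTPases, had 117 ± 10.8 CPM in controls and 138 ± 6.02 CPM in heterozygotes (SD, n = 8 each), a log2 difference of 0.25 (SE 0.04). Cnr1, the cannabinoid receptor CB1, had 614 ± 39.6 CPM in controls and 752 ± 60.7 CPM in heterozygotes, a log2 difference of 0.29 (SE 0.05). For each of these genes, 7 of the 8 controls lay below every heterozygote. By edgeR's quasi-likelihood test, 0 of 16487 genes passed, with 934 at an unadjusted p under 0.05, and Rasgef1b and Cnr1 had adjusted p = 0.34. Limma voom called 0 genes (854 at an unadjusted p under 0.05) and DESeq2 called 2 (1072), Rasgef1b (adjusted p = 8.1e-05) and Cnr1 (adjusted p = 0.00052).

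Of the 20 genes with the smallest p, 15 were higher and 5 lower in heterozygotes, and none of them passed edgeR (18 of them at adjusted p = 0.75). Camk4, a calcium and calmodulin dependent kinase, had 766 ± 84.5 CPM in controls and 941 ± 57.4 CPM in heterozygotes (log2 difference 0.30). Pde7b, a cAMP phosphodiesterase, had 284 ± 23.0 and 336 ± 21.6 CPM (0.24). The sodium channel subunit Scn4b had 2033 ± 151.8 and 2341 ± 119 CPM (0.20), and the calcium pump Atp2b1 1838 ± 129 and 2126 ± 131 CPM (0.21). The activin receptor Acvr1c (0.30), Rgs7bp (0.28), Gpr155 (0.24), Epyc (0.25), the transcription factors Dach1 (0.23) and Bcl11b (0.20), and the gene models BC031361 (0.26), Gm17769 (0.42) and 5830416I19Rik (0.58) made up the rest of the higher genes. Lower in heterozygotes were Rnd3 (24.3 ± 6.34 CPM in controls, 15.3 ± 3.29 CPM in heterozygotes, log2 difference -0.67), the zinc finger gene Zfp811 (-0.35), the collagen gene Col26a1 (-0.32), Izumo4 (-0.27) and the gene model Gm2897 (-0.58). The count of passing genes moved with single mice, since leaving out control mouse 7 added Rasgef1b and leaving out control mouse 9 added Acvr1c. Without control mice 1 and 9 it was 41, while without mice 9 and 11, and without mice 1, 9 and 11, edgeR called 0 genes, with 1231 and 1554 at an unadjusted p under 0.05. In the 14 mice left without mice 1 and 9, cortical neuron genes were also lower in heterozygotes (median of limma voom values -0.60, camera adjusted p = 3.1e-06), against a median of 0.14 in all 16 mice. This camera call is at its preset correlation. It was lost with an estimated correlation (adjusted p = 0.65) and by fry (adjusted p = 0.35). Mice 1 and 9 had the lowest cortical scores of the 16 mice (-2.085 and -0.821). Leaving them out raises the control mean of this list, so its direction there depends on which mice were left out.

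Genes of medium spiny neurons, the main neuron type of the striatum, were slightly higher in heterozygotes as a group. Of the 20 list genes, 19 had a higher fitted value in heterozygotes, with a median log2 difference of 0.08. The transcription factors Bcl11b (log2 difference 0.20, SE 0.05) and Foxp1 (0.155, SE 0.05) and the Ras-like protein Rasd2 (0.21, SE 0.05) passed when adjusted over the list alone, and 0 list genes passed over all genes. Limma's camera called the list higher (adjusted p = 1.9e-07), and the call was lost with adjusted p = 0.19 with an estimated correlation and adjusted p = 0.087 by fry. With the cortical score as covariate the list passed both (adjusted p = 0.047 with an estimated correlation, 0.0095 by fry). Fry also called it without mouse 1 (adjusted p = 0.013), without mice 1 and 9 (0.0085) and with both tissue scores as covariates (0.026). Fry did not call it without mouse 2, 3, 4, 5 or 6 (adjusted p = 0.18, 0.20, 0.058, 0.165 and 0.16). Mouse 1 had the highest list score of the controls (0.048), so leaving it out widens the difference between genotypes. The list score was -0.055 ± 0.074 in controls and 0.055 ± 0.035 in heterozygotes (SD, n = 8 each, exact permutation p = 0.0014, 0.038 after Benjamini-Hochberg adjustment over 27 scores). The difference of the scores was 0.104 in males and 0.115 in females (exact permutation p of their difference = 0.91). In the 5 cages that held both genotypes it was 0.165, 0.055, 0.072, 0.257 and 0.092.

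**Figure D2:**
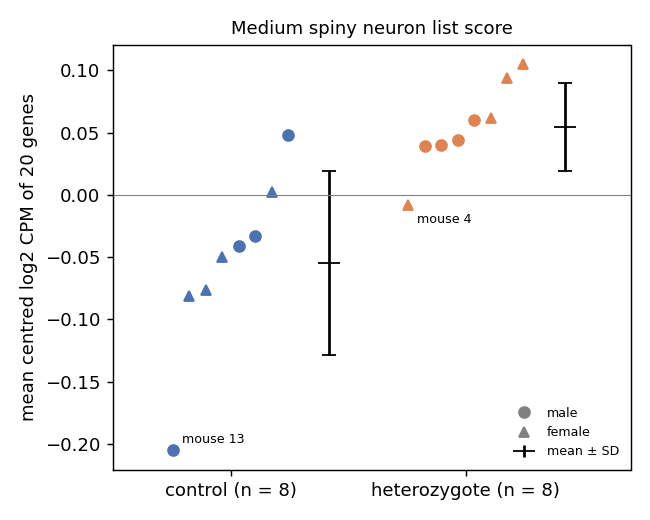
Score of the 20 medium spiny neuron genes per mouse, as mean centred log2 CPM (y axis), by genotype (x axis), with circles for males, triangles for females and bars for the mean ± SD of 8 mice. The mean is -0.055 in controls and 0.055 in heterozygotes, and the lowest value is that of control mouse 13.

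Genes of direct-pathway spiny neurons were higher in heterozygotes in 7 of 10 cases, with a median log2 difference of 0.07. The dopamine receptor gene Drd1a (0.11) and the muscarinic receptor gene Chrm4 (0.18) were among those with the smallest p and did not pass. Camera called the list (adjusted p = 0.035), with adjusted p = 0.50 with an estimated correlation, and the score had exact permutation p = 0.015 (0.20 after Benjamini-Hochberg adjustment, n = 8 each). The call was lost without mouse 3, 6, 13, 15 or 16 (camera adjusted p = 0.056, 0.095, 0.20, 0.055 and 0.064), and the median of voom values went from 0.08 to 0.041 without mouse 13. Of the indirect-pathway genes, 7 of 10 were higher (median 0.06), among them Plxdc1 (0.175), Gucy1a3 (0.14) and the dopamine receptor gene Drd2 (0.12), and camera did not call the list (adjusted p = 0.12). It did so without heterozygous mouse 4 or control mouse 9 (camera adjusted p = 0.0097 and 0.0067), both at its preset correlation. Without mouse 4 the adjusted p was 0.24 with an estimated correlation and 0.59 by fry. The median of voom values, 0.068 with all mice, ran from 0.02 without mouse 13 to 0.108 without mouse 4.

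Synaptic receptor genes were also higher as lists. Glutamate receptor and postsynaptic density genes were higher in 28 of 34 cases (median log2 difference 0.08), with Nlgn1 at 0.17, Dlgap3 at 0.16 and Grik2 at 0.13, and GABA genes in 16 of 21 cases (median 0.08), with the scaffold gene Gphn at 0.12 and the vesicular transporter Slc32a1 at 0.14. None of these genes passed by edgeR. Camera called both lists (adjusted p = 3.0e-06 and 0.015), with adjusted p = 0.64 with an estimated correlation for each. Control mouse 9 had the lowest glutamate score (-0.828) and GABA score (-0.363) of the controls, and without it the median of limma voom values went from 0.10 to 0.017 for glutamate genes and from 0.08 to 0.033 for GABA genes (camera adjusted p = 0.084 and 0.018). The GABA list lost its call without mouse 1, 6 or 13 (medians 0.081, 0.039 and 0.047, camera adjusted p = 0.055, 0.050 and 0.072). With the 3' coverage index as covariate, camera called neither list (adjusted p = 0.56 and 0.075). The index was 1.08 in mouse 9 and -0.0351 to 0.112 in the other mice. Here and below this covariate therefore largely marks mouse 9, and it does not test coverage across the other mice.

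Nuclear genes of oxidative phosphorylation were lower in heterozygotes in 51 of 51 cases (median log2 difference -0.15), with Ndufa2 at -0.29, Ndufa5 at -0.27 and Cox7a2 at -0.22, and heat shock genes in 15 of 15 cases (median -0.16), with Hspa1a at -0.59, Hspb1 at -0.49 and Hspe1 at -0.32. No gene of these lists passed by edgeR. Camera called both lists (adjusted p = 7.9e-05 and 0.015), with adjusted p = 0.645 and 0.64 with an estimated correlation. These differences moved with control mouse 9, whose oxidative phosphorylation score was 0.877 and whose heat shock score was 1.166, against a range of -0.121 to 0.036 and -0.321 to 0.364 in the other mice. Without mouse 9 the medians of limma voom values went from -0.11 and -0.13 to 0.008 and -0.015, and camera called neither list (adjusted p = 0.39 and 0.82). Camera called oxidative phosphorylation in the opposite direction, higher in heterozygotes, with the 3' coverage index as covariate (41 of 51 genes, adjusted p = 8.7e-05) and without mice 1 and 9 (37 of 51 genes, adjusted p = 0.014). That index largely marks mouse 9, so the fit with it is no check apart from that mouse. Heat shock also lost its call without mouse 1, 2 or 10 (camera adjusted p = 0.094, 0.086 and 0.12).

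Genes of ependymal cells, which line the ventricles, were lower in heterozygotes in 13 of 13 cases (median log2 difference -0.57), among them the cilium genes Ccdc153 (-0.89), Enkur (-0.66) and Tekt1 (-0.57). Camera called the list (adjusted p = 0.00029), with adjusted p = 0.64 with an estimated correlation. The scores were 0.212 ± 0.77 in controls and -0.212 ± 0.382 in heterozygotes (SD, n = 8 each). Their difference had exact permutation p = 0.19, and 0.73 after Benjamini-Hochberg adjustment. Control mouse 9 had an ependyma score of 1.552, and without it the median of voom values went from -0.45 to -0.255 (camera adjusted p = 0.036), against -0.59 to -0.38 without any other single mouse. Camera did not call the list with the 3' coverage index (median -0.205, adjusted p = 0.10) or both tissue scores (median -0.13, adjusted p = 0.15) as covariates. Activity-regulated immediate early genes were lower in 20 of 23 cases (median -0.24), with Nr4a1 at -0.74, Per1 at -0.33 and Fosl2 at -0.54. Camera called this list (adjusted p = 0.031), with adjusted p = 0.64 with an estimated correlation. Leaving out any of 8 single mice (1, 3, 4, 5, 6, 8, 9 or 15) ended that call, with camera adjusted p from 0.055 to 0.29. The median of voom values, -0.195 with all mice, was -0.10, -0.093 and -0.13 without mouse 3, 6 or 8 and -0.31 without mouse 12.

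The other 18 lists were not called by camera (adjusted p from 0.10 to 0.79). Among neuronal lists, striatal interneuron genes were higher in heterozygotes in 2 of 13 cases (median log2 difference -0.11, with Calb2 at -0.60, Kit at 0.05 and Nos1 at 0.35), dopamine synthesis and transport genes in 4 of 12 (-0.06, with Slc18a2 at -0.26, Ret at -0.38 and Maob at -0.06), and presynaptic vesicle genes in 16 of 27 (0.05, with Syn3 at 0.21 and Nsf at 0.10). Neuropeptide, opioid and cannabinoid genes were higher in 6 of 21 cases (median -0.08, with Dagla at 0.21 and Nts at -0.46), although camera's direction for this list was up, and Cnr1 passed when adjusted over the list alone. Of the hnRNP family, which includes Hnrnph1, 6 of 26 genes were higher (median -0.03, with Hnrnpul2 at 0.08, Hnrpll at -0.11 and Hnrnpab at -0.12). Of the other splicing factors, 15 of 47 were higher (median -0.03, with Rbfox3 at 0.15, Rbfox1 at 0.13 and Mbnl2 at 0.12). The neighbours of Hnrnph1 on chromosome 11 were higher in 9 of 14 cases (median 0.01, with Zfp879 at 0.26, Mapk9 at 0.06 and Adamts2 at 0.22). Single mice turned the direction of 3 of these lists. Without heterozygous mouse 4 the median of limma voom values of interneuron genes went from -0.094 to 0.038, with 8 of 13 higher, and without control mouse 1 to -0.235. Without control mouse 9 that of the hnRNP family went from -0.020 to 0.006, with 16 of 26 higher, and without control mouse 13 to -0.041. Without heterozygous mouse 12 that of neuropeptide genes went from -0.031 to 0.014, and without control mouse 1 to -0.084. That of presynaptic genes went from 0.053 to 0.014 without control mouse 9 and to 0.085 without control mouse 3. That of dopamine genes was -0.067 to -0.015 and that of the neighbours of Hnrnph1 0.008 to 0.032 without single mice. Camera called the presynaptic list without mouse 3, 4 or 5 (adjusted p = 0.011, 0.042 and 0.020). These calls were lost with an estimated correlation (adjusted p = 0.58, 0.73 and 0.64) and by fry (adjusted p = 0.54, 0.59 and 0.47).

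Among lists of other cells, astrocyte genes were higher in 9 of 16 cases (median log2 difference 0.005 and mean -0.004, with Slc4a4 at 0.24, Gfap at -0.195 and Sox9 at -0.08), oligodendrocyte genes in 9 of 17 (0.005, with Mobp at 0.09, Myrf at 0.10 and Gjc3 at 0.04) and oligodendrocyte precursor genes in 8 of 10 (0.04, with Cspg4 at 0.14, Ptprz1 at 0.10 and Sox6 at 0.12). Microglial genes were higher in 5 of 17 (-0.04, with Aif1 at -0.25, Ctss at -0.16 and Tyrobp at -0.16) and endothelial and mural genes in 11 of 20 (0.04, with Pecam1 at 0.09, Tagln at -0.24 and Acta2 at -0.17). Choroid plexus genes were higher in 2 of 15 (-0.63, with Sostdc1 at -1.32, Folr1 at -1.05 and Otx2 at -0.90) and meningeal genes in 4 of 13 (-0.11, with Slc13a4 at -0.42, Aldh1a2 at -0.25 and Igfbp2 at -0.26). For tissue next to the striatum, cortical genes were higher in 3 of 15 (-0.28, with Fezf2 at -0.43, Rprm at -0.26 and Neurod6 at -0.43), with camera's direction and the median of limma voom values (0.14) up, and genes of septum, pallidum and thalamus in 4 of 15 (-0.27, with Zic2 at -0.64, Trpc4 at -0.54 and Gbx1 at 0.48). Of the haemoglobin list, Alas2 was at 0.055. Sex-linked genes were higher in 8 of 9 cases (0.08, with Ddx3x at 0.055, Ddx3y at 0.255 and Uty at 0.25). None of the genes named for these lists passed by edgeR over all genes.

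Several of these lists moved with single mice, by the median of limma voom values. Without control mouse 9 that of choroid plexus genes went from -0.27 to 0.075, with 9 of 15 higher, and that of microglial genes from -0.035 to 0.005, with 9 of 17 higher (-0.063 without control mouse 3). That of oligodendrocyte precursor genes went from 0.048 to 0.002, with 5 of 10 higher, and that of sex-linked genes from 0.114 to 0.008, with 6 of 9 higher. Without control mouse 1 that of cortical genes went from 0.14 to -0.17, and without control mouse 13 to 0.236. That of septum, pallidum and thalamus genes, -0.126 with all mice, ran from -0.277 without control mouse 1 to -0.087 without heterozygous mouse 16. Those of endothelial and meningeal genes were 0.024 to 0.059 and -0.123 to -0.042 without single mice. The medians of astrocyte and oligodendrocyte genes, 0.005 and 0 with all mice, lay between -0.014 and 0.021 and between -0.054 and 0.037 without single mice. The oligodendrocyte list was at -0.054 without heterozygous mouse 4, where camera called it (adjusted p = 0.043). Camera also called choroid plexus without mouse 3 or 13 (adjusted p = 0.029 and 0.0485). It called septum, pallidum and thalamus without mouse 3 (adjusted p = 0.029) and meninges without mouse 8 or 11 (adjusted p = 0.034 and 0.042). All these calls are at its preset correlation. With an estimated correlation, adjusted p was 0.73 for the oligodendrocyte list without mouse 4. Without mouse 3 it was 0.58 for choroid plexus and 0.58 for septum, pallidum and thalamus. Of the 98 genes named for this comparison, 44 moved by more than 1.5 times without control mouse 9 by edgeR. Nos1 went from 0.35 to 0.15, Calb2 from -0.60 to -0.27, Nts from -0.46 to -0.10, Syn3 from 0.21 to 0.09, Sox6 from 0.12 to 0.004 and Ddx3y from 0.255 to 0.09.

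The genotype effect was also estimated within each sex. In males the smallest p were those of Strip2 (log2 difference 0.49, SE 0.09), Camk4 (0.43), Fam198b (0.41), Hecw2 (0.385) and Rasgef1b (0.30) among the higher genes, and Pdlim7 (-0.43, SE 0.08), Tnfsf9 (-1.14), Gpt (-0.43), Tmem39a (-0.36) and Phf1 (-0.325) among the lower ones. In females they were Cnr1 (0.365, SE 0.07), Osbpl3 (0.37), Ivns1abp (0.17), Rasgef1b (0.20) and Tbx3 (0.40), and Zfp811 (-0.44, SE 0.11), Fank1 (-0.605), Trp53tg5 (-0.68), Clec11a (-0.63) and Htr1a (-0.95). Control mouse 9, whose transcript coverage was shifted to the 3' end, is 1 of the 4 male controls. Its Camk4 level was 571.8 CPM, against 753.4 CPM in the next lowest control. The male values here and in the interaction below are not given without it. By edgeR, 0 genes passed in males, with 2133 at an unadjusted p under 0.05, and 0 in females, with 433. No other tool was run on the sexes, and a fit of each sex alone by edgeR also called 0, with 610 and 1406.

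The difference between the sexes in the genotype effect was tested itself. Its smallest p were those of Mir7-1 (log2 difference -0.91 in males and 0.45 in females), Phf1 (-0.325 and 0.07), P4ha1 (-0.505 and 0.22), Col11a2 (-0.19 and 0.25) and Fam193b (-0.205 and 0.14) in one direction, and Bmp8b (1.21 and -0.945), Zfp941 (0.30 and -0.20), Gda (0.19 and -0.31), Il1r2 (0.67 and -0.46) and Strip2 (0.49 and 0.015) in the other. By edgeR, 0 of 16487 genes passed this interaction (adjusted p = 0.75 for each of these 10), with 860 at an unadjusted p under 0.05. DESeq2 also called 0 (1013 at an unadjusted p under 0.05), as did limma voom (895).

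Sex differences gave 12 genes past edgeR's test, 7 higher and 5 lower in females, with 683 at an unadjusted p under 0.05. The Y-linked genes Ddx3y (89.9 ± 6.28 CPM in males, 0.292 ± 0.221 in females, SD, n = 8 each), Eif2s3y, Uty, Kdm5d and Uba1y were lower in females, by log2 differences of -8.23, -8.26, -8.11, -8.13 and -6.95. Xist, the RNA of X inactivation, had 9.00 ± 9.59 CPM in males and 1610 ± 179 CPM in females, and Tsix, which overlaps it on the opposite strand, 0.903 ± 0.397 and 83.6 ± 11.7 CPM. The X-linked Eif2s3x (0.56, SE 0.04), Ddx3x (0.38, SE 0.04) and Kdm6a (0.58, SE 0.09), which have Y-linked relatives, were higher in females (edgeR adjusted p = 3.3e-07, 9.8e-05 and 0.014), as were the gene models 1700030C10Rik (1.25) and 5530601H04Rik (0.40). Because the counting's strand setting is not stated, the values of Xist and Tsix are uncertain. DESeq2 called 20 genes, 11 of them shared, and gave Xist no adjusted p, and Kdm6a did not pass without heterozygous mouse 10 (edgeR adjusted p = 0.052).

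Exon usage differed between the genotypes at 1 bin, in Ntrk2 (ENSMUSG00000055254, chromosome 13, 58806569 to 59133970, GRCm38), which encodes the BDNF receptor TrkB. The usage of its bin 15 of 22 fell by 0.80 on the log2 scale in heterozygotes (SE 0.117, edgeR adjusted p = 2.3e-05). This is a weakly covered bin, with 0.534 to 3.051 CPM in controls and 0.251 to 0.745 CPM in heterozygotes, against 104.2 to 190.4 CPM for bin 16 of Ntrk2 in the same mice. The highest value was that of control mouse 9, and without it Ntrk2 did not pass (log2 difference -0.47, adjusted p = 0.197) and edgeR called a bin of Hdac1 instead. The gene-level F test of edgeR called 135 genes with changed usage. Without single mice it called 11 to 818 (11 without mouse 2, 12 without mouse 14, 13 without mouse 9, of which 1 was shared, and 818 without mouse 5), and without control mice 1 and 9 it called 6. On simulated data the exon test made more false calls than its nominal rate.

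Control mouse 9 stood apart from the other 15 mice, with a value of 95.7 on the first principal component, which held 41.7% of the variance, and between -16.26 and 6.58 in the others. Its transcript coverage was shifted to the 3' end, with an index of 1.08 against -0.035 to 0.112 in the other mice, although its RNA integrity number was 10. Its library also held 370 CPM of the choroid plexus gene Ttr, against at most 12.64 CPM in the others. Nos1, a gene of a striatal interneuron type, was at 3.01 CPM in mouse 9 and 32.16 to 45.06 CPM in the others, while Sst (225.2 CPM) and Npy (58.76 CPM), also genes of striatal interneurons, were higher in mouse 9 than in any other mouse.

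**Figure D3:**
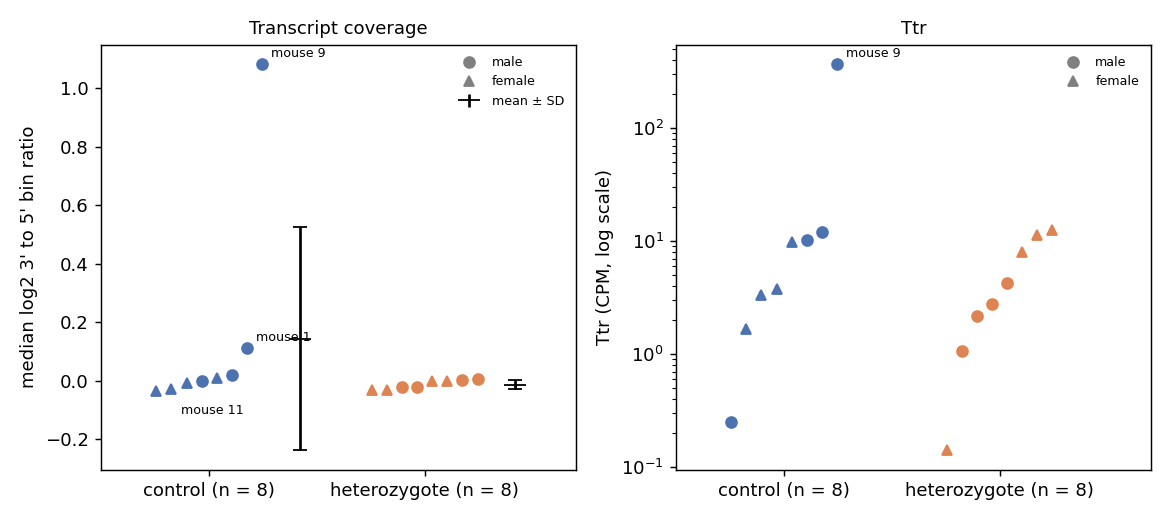
Index of 3' coverage (left, median log2 ratio of 3' to 5' bin counts) and Ttr level (right, CPM on a log axis) per mouse, with circles for males, triangles for females and, on the left, bars for the mean ± SD of 8 mice. Control mouse 9 has an index of 1.08 and 370 CPM of Ttr.

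Heterozygous mouse 4 had low levels of genes of cholinergic interneurons. Chat, the enzyme of acetylcholine synthesis, was at 1.75 CPM, against 20.3 ± 3.31 CPM in the other mice (SD, n = 15). The choline transporter Slc5a7 was at 3.09 CPM against 46.3 ± 6.20, the vesicular transporter Slc18a3 at 0.719 against 8.80 ± 1.07, the glutamate transporter Slc17a8 at 1.34 against 21.2 ± 2.37, and the transcription factor Lhx8 at 1.92 against 6.21 ± 1.21 CPM. Of genes of other interneurons, Sst (130.6 CPM), Npy (42.3), Pvalb (18.4) and Nos1 (44.0) were not low in this mouse, while Th was at 3.16 CPM, below the 5.95 to 9.52 CPM of every other mouse. The other 7 heterozygotes had 21.2 CPM of Chat on average and the controls 19.4 CPM.

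**Figure D4:**
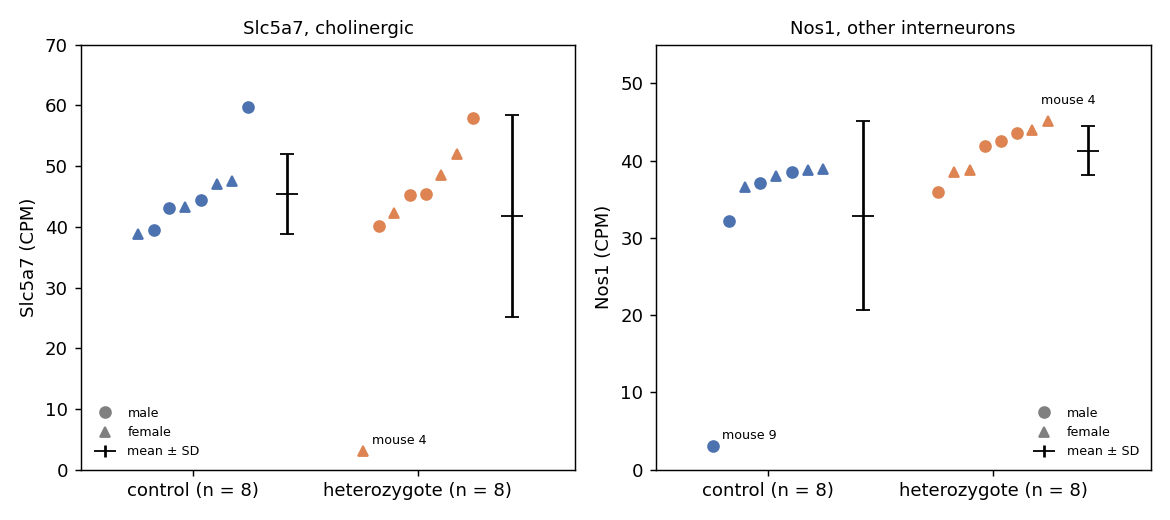
Levels of the cholinergic gene Slc5a7 (left) and of Nos1, a gene of another interneuron type (right), per mouse in CPM, with circles for males, triangles for females and bars for the mean ± SD of 8 mice. Heterozygous mouse 4 has 3.09 CPM of Slc5a7 and 44.0 CPM of Nos1, and control mouse 9 has 3.01 CPM of Nos1.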

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

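Among the tests below, those of coverage and of a swap for mouse 9 and that of the knockout for mouse 4 were chosen after the result was seen. Of 104 groups of 8 mice (52 measures in each genotype), 24 held a mouse far from the other 7, and chance flags about 1 in 20 groups. Of these 24 values, 15 belong to control mouse 9, 3 to heterozygous mouse 4 and 2 to control mouse 1, while mice 6, 7, 10 and 11 have 1 each.

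Control mouse 9 lay far from the other 7 controls in 15 measures. Its reads outside any gene (48.1%) were low and those ambiguous between genes (0.301%) high, and its index of 3' coverage was 1.08. Its scores were high for choroid plexus (2.076), heat shock (1.166), oxidative phosphorylation (0.877) and the hnRNP family (0.28). They were low for glutamate (-0.828), presynaptic (-0.511), oligodendrocyte precursor (-0.408) and GABA genes (-0.363). Hnrnph1 was high (427.6 CPM), while Acvr1c (94.5 CPM), Camk4 (571.8 CPM) and Rgs7bp (427 CPM) were low.

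For mouse 9, choroid plexus and ependymal tissue in the punch as the whole cause is argued against by medium spiny neuron genes, which were also shifted to the 3' end (index 1.18, against -0.0597 to 0.184 in the other 15 mice). A swap with mouse 11, the female with an RNA integrity number of 8.3, is argued against by Ddx3y, which was at 77.2 CPM in mouse 9 and at most 0.801 CPM in females, although it lay slightly below the other males (83.7 to 94.3 CPM). Coverage shifted to the 3' end over all genes (1.08, against -0.0351 to 0.112) stays open and is consistent with a library made from partly degraded RNA. Extra choroid plexus tissue beside it also stays open, given the 370 CPM of Ttr. No biological explanation was tested.

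Heterozygous mouse 4 lay far from the other 7 heterozygotes in its interneuron score (-1.101), its indirect-pathway score (-0.172) and its oligodendrocyte score (0.386). For its low cholinergic genes, a faulty run is argued against by Chat, which lay below every other mouse in all 4 runs. The heterozygous knockout as such is argued against by the other 7 heterozygotes, whose 5 cholinergic list genes differed from controls by 0.081 on the log2 scale. A punch that missed ventral or medial tissue would likely lower the septum, pallidum and thalamus score, which was -0.266, within the range of the other 15 mice (-0.448 to 0.721). A loss of cholinergic neurons or of their expression in this mouse stays open and was not tested, and Th, a gene of another interneuron type, was also low (3.16 CPM).

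Control mouse 1 had the lowest interneuron score (-0.228) and neuropeptide score (-0.566) of the controls. Control mouse 7 had the lowest score of other splicing factors among controls (-0.054). Heterozygous mouse 10 had the highest oxidative phosphorylation score among heterozygotes (0.036). Heterozygous mouse 6 had the highest Hnrnph1 level among heterozygotes (382.6 CPM). Control mouse 11 had the most reads in exon bins (124907218).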

How the results depend on the processing

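Chosen after the data were seen were sample quality weights, robust dispersions, leaving out several mice, the F test without mouse 9, and leaving out mice or adding covariates for gene lists. No paired analysis was possible because controls and heterozygotes share no mouse number and the labels name no pairs. As substitutes, blocks of cage and of consecutive numbers each gave 0 genes by edgeR (1350 and 857 at an unadjusted p under 0.05), as did cage as a random effect in limma voom (1086), while DESeq2, without a block, gave 2. Over all alternatives, comparisons moved in 27 cases, weakened in 2 and stayed in 175.

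Genes between genotypes went from 0 by edgeR (934 at an unadjusted p under 0.05) to 2 with DESeq2, 1 with surrogate variables, 5 with sample quality weights, 272 with 64 runs and the mouse as a random effect, and 41 without mice 1 and 9. Leaving out 1 mouse gave 0 to 1 genes (1 without mouse 7 or mouse 9). Males, females and the interaction gave 0 to 0 by edgeR, with 2133, 433 and 860 at an unadjusted p under 0.05 (1354 to 3842, 216 to 1136 and 579 to 1974 without single mice). Genes between sexes went from 12 to 20 with DESeq2, and to 9 to 15 without single mice. The cause was not tested.

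Exon usage gave 2 bins in 2 genes with limma's diffSplice, 0 without mice 1 and 9 (edgeR), 135 genes with the gene-level F test and 13 with that test without mouse 9. Without single mice there were 1 to 2 bins and 1 to 3 genes (2 bins without mouse 1, 5, 12 or 13). Called lists went from 8 to 0 with an estimated correlation and to 0 by fry. With the 3' coverage index, which largely marks mouse 9, as covariate camera called 4 lists. They were medium spiny neuron, direct pathway, indirect pathway (not called before) and oxidative phosphorylation (then higher). Without single mice camera called 5 to 10 (5 without mouse 1, 6 or 9). Both of these counts are at its preset correlation of 0.01. The medium spiny neuron list lost its call with an estimated correlation and by fry (median of voom values 0.09 in each) and passed both with the cortical score as covariate (adjusted p = 0.047 and 0.0095), and its median was 0.067 to 0.115 without single mice. The cause was not tested.

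Among named genes and the 8 called lists, directions reversed in 31 cases. Without mice 1 and 9, and without mice 1, 9 and 11, the values were 0.017 and 0.019 for Hspa1a, 0.024 and 0.014 for Hspb1, 0.028 and 0.019 for Hspe1, and 0.011 and 0.021 for Tyrobp. Mapk9 was at -0.004 without mice 1, 9 and 11. Without mice 9 and 11, Myrf was at -0.015, Gjc3 at -0.015 and Sox6 at -0.002. Sox6 was at -0.010 with surrogate variables, Mobp at -0.002 with counts summed over bins, and Gjc3 at -0.025 without mouse 4 (-0.025 to 0.082 over single mice). Neurod6 was at 0.331 with limma voom, 0.216 with cage as a random effect, 0.032 with the block of numbers, 0.212 with 64 runs and 0.165 with surrogate variables. In single runs Aldh1a2 was at 0.048 and Alas2 at -0.091 and -0.069, and Alas2 was at -0.022 to 0.12 over single mice (below 0 without mouse 3, 13 or 16). The oxidative phosphorylation list was at 0.008 without mouse 9 (-0.151 to 0.008 over single mice), 0.022 without mice 1 and 9 and 0.033 with the 3' coverage index. Camera called it higher in the last 2, at its preset correlation. The heat shock list was at 0.034 without mice 1 and 9 and 0.012 with that index. The cause was not tested.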

Other observations

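The counts of other splits of the mice were chosen after the results were seen, except that for the number of called lists, as were the tests of mouse 9 and of the permutation p for the medium spiny neuron list. Each number of splits with as many calls includes the real one. For genes between genotypes, males, females and the interaction, the real count by edgeR was 0, which every split reaches (100 of 100, 35 of 35, 35 of 35 and 100 of 100, highest other 2, 0, 0 and 0), so these counts say nothing on chance. For the sexes, 1 of 100 splits, the real one, gave as many as its 12 genes (highest other 1), which excludes chance. For exon usage, 10 of 24 splits gave as many as the real 1 bin and 10 of 24 as many as the real 1 gene, so chance cannot be excluded. The highest other split called 68 bins in 29 genes, which points to a structure of the samples. The cause was not tested, and false calls of the exon test, seen on simulated data, are not excluded. By the gene-level F test, 9 of 24 splits gave as many as the real 135 genes (highest other 4218), so chance cannot be excluded.

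With 64 runs and the mouse as a random effect, 7 of 100 splits gave as many as the real 272 genes (highest other 358), so chance cannot be excluded. The fit used 1 correlation between runs of a mouse for all genes (0.754). Without mice 1 and 9, 1 of 100 splits, the real one, gave as many as its 41 genes (highest other 2). These splits do not repeat the choice of the mice left out, which was made after their values were seen, so they leave chance open. Of these genes 10 were higher and 31 lower in heterozygotes, led by Gabra3 (-0.44), Elavl4 (-0.41), Ppp1r26 (-0.26) and Acvr1c (0.24). Without the same mice the cortical list was lower in heterozygotes (median of limma voom values -0.60, 1 of 15 genes higher, camera adjusted p = 3.1e-06). That call is at camera's preset correlation, and it was lost with an estimated correlation (adjusted p = 0.65) and by fry (adjusted p = 0.35). The left-out mice 1 and 9 had the lowest cortical scores of all mice (-2.085 and -0.821), so this direction depends on their removal. Whether the 41 genes follow the tissue in the punch was not tested. Mice 1 and 9 are both controls, and without mice 9 and 11, and without mice 1, 9 and 11, edgeR called 0 genes (1231 and 1554 at an unadjusted p under 0.05). For gene lists, 67 of 100 splits gave as many as the real 8 called lists (highest other 15), so chance cannot be excluded for their number. The medium spiny neuron list had the smallest camera adjusted p (1.9e-07), and in 77 of 100 splits some list had one as small (smallest other 1.2e-19), so chance cannot be excluded for this call. The list itself was called in 39 of 100 splits, the real one included. It had an adjusted p as small in 2 of them, the real one and 1 other.

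Medium spiny neuron genes may be slightly more abundant in heterozygous striatum, a hypothesis from a score difference of 0.109 (exact permutation p = 0.0014, n = 8 each). The 3' shifted library of mouse 9 is argued against as its cause by a difference of 0.111 without that mouse. With the cortical and the septum, pallidum and thalamus scores in the model the difference was 0.115, so these scores did not account for it. For cortical tissue this cannot decide, because the cortical score was not higher in controls (-0.073 ± 1.06, heterozygotes 0.073 ± 0.475, SD). The ependyma scores (0.212 in controls, -0.212 in heterozygotes) and choroid plexus scores (0.164 and -0.164) were not in the model. More tissue from outside the striatum in control punches therefore stays open. The position of the punch within the striatum, and litter or cage effects beyond the 5 mixed cages, stay open and were not tested.

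Over the 16 mice the medium spiny neuron score and the cortical score had Pearson's r = -0.41 (permutation p = 0.12) and Spearman's rho = -0.46 (permutation p = 0.073), with 0.47 and 0.29 after Benjamini-Hochberg adjustment over 4 relations. Without the 2 mice farthest from the median cortical score r was -0.23. Within controls r was -0.76 (exact permutation p = 0.033, n = 8) and rho -0.86 (exact permutation p = 0.011), with 0.24 and 0.086 after Benjamini-Hochberg adjustment over 8 relations, and r was -0.555 without the 2 farthest mice. Within heterozygotes r was -0.31 and rho -0.50 (exact permutation p = 0.47 and 0.22, n = 8). No relation passed the adjustment.

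In heterozygous mouse 6, among genes picked after their values were seen, Zbtb16 was at 39.1 CPM, against at most 9.95 CPM in the other mice, Fkbp5 at 82.4 CPM, Tsc22d3 at 79.5 CPM and Plin4 at 33.5 CPM. Mouse 9, which shared a cage with mouse 6, also had 73.5 CPM of Fkbp5, 121.8 CPM of Tsc22d3 and 11.5 CPM of Plin4. Its Zbtb16 level went the other way, at 5.07 CPM, the lowest of all mice, and its library was shifted to the 3' end. Control mouse 1 had a cortical score of -2.09, the lowest of the 16, and stood apart on the third principal component (-39.1). The second component, with 13.5% of the variance, separated the sexes except for mice 1 and 3. The cortical score of female mouse 3 was 0.942, the highest among females. Whether this component follows sex or the tissue in the punch was not tested.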
